A study of Mus musculus with 12 samples.

How the data were processed

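Total RNA of whole spinal cord was sequenced as 75-base paired reads from stranded polyA libraries, per the labels' protocols. Each of the 12 libraries had its own deposited table of 38924 Ensembl genes. Per the submitters' processing notes, Bowtie2 2.2.0 and RSEM 1.2.12 were used. The genome build and annotation release are not given in the sources used here. Per the file headers, the authors' RSEM output held an expected count per gene, TPM, FPKM, length and effective length. RSEM divides reads that fit several genes among them, so the deposited expected counts need not be whole, and values of close paralogs and of overlapping genes are uncertain. Deposited TPM was used only in alternatives. The deposited FPKM was not used.

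Expected counts were rounded to whole numbers. Genes were kept by filterByExpr with the 4 titled groups, which left 17765 genes. Counts were scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors were computed from the fitted log2 difference and its F statistic, as the difference divided by the square root of F. CPM are counts scaled by TMM to a common library size. Genotype over all libraries was tested with titled sex as a term, and titled sex with title genotype as a term. Genotype within each titled sex and the difference between the sexes came from 1 fit with a mean for each of the 4 groups. For genes with 3 counts or fewer in a group, a ratio with its exact 95% interval is given in place of the fitted value. Where the group had 0 counts, a ratio against a floor of 3 counts over the group is given, with the exact lower 95% bound. Reads carried no molecular identifiers, so intervals and floors cover counting error only.

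The groups follow the titles. The labels do not say in so many words that each library came from a separate animal, so p-values measure the spread between these libraries. No 2 libraries agreed within sampling noise: over the 66 pairs the chi-square per degree of freedom was at least 5.8, on genes with over 120 counts in sum, and the correlation of log2 CPM was between 0.98575 and 0.99667. No library was inferred to belong to another group from its values.

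Before the data were examined, 44 gene lists of stress responses, cell types, pathways and neighbouring tissues were fixed, and 43 were tested, leaving out the sex-linked list. The test was camera of limma 3.58.1 with a preset correlation of 0.01, for lists with at least 5 tested members. Each list was also tested with an estimated correlation and with fry, which asks whether the members move on balance one way and does not compare them with other genes. Positions came from GENCODE M21, matched by Ensembl gene ID for 37607 IDs (96.62%). Composition measures were compared by exact permutation tests, two-sided, over 400 splits within titled sex, and over 924 splits for the library name.

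Genes are named by a rule fixed at the same time. Gars comes first. In each comparison the rule takes the 10 largest and 10 lowest log2 differences among called genes with an established name, and the 5 of lowest p in each direction. All called genes are taken where fewer than 20 pass, and the 10 of lowest p, as not passing, where fewer than 5 pass. It adds up to 4 called members of each list, or otherwise the 2 of lowest p, 6 sex-linked genes and up to 5 autosomal genes per direction for sex, and called genes within 20 Mb of Gars. Genes outside the rule are marked as chosen after their values were seen.

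Other settings fixed in advance were DESeq2 1.42.0, RLE size factors, no filter on low counts, a mean above 1 CPM, limma on log2(TPM + 1) and log2(TPM + 0.1), voom with quality weights, 1 surrogate variable (sva 3.50.0), no sex term, the library-name genotype, the 8 undisputed libraries, other windows around Gars, and leaving out each library in turn. The same settings for the library-name genotype, its gene lists, position test and composition, the fit without 4 libraries holding over 0.15% skeletal muscle transcripts, and the library number as a linear term, were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for joins, permutations and plots.

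The fits were tested on simulated data of 17765 genes, 50 of them changed at each size. For the 6 against 6 comparison by title, 42, 72, 74 and 98% of the genes changed 1.25, 1.5, 2 and 4 times were recovered, with 7 false calls. For the 6 against 6 comparison by library name the shares were 34, 66, 80 and 100%, with 6 false calls. For the 8 undisputed libraries they were 18, 52, 80 and 88%, with 6 false calls, and for the titled sexes 54, 76, 88 and 96%, with 6. For 3 against 3 among females they were 16, 52, 70 and 92%, with 9 false calls. Among males they were 16, 58, 90 and 92%, with 8. For the difference between the sexes they were 0, 42, 62 and 84%, with 2. Every simulation took its spread from the fit by library name and assumed the labels under test to be right. The shares for titled groups can therefore overstate what the real fits find. Among the real libraries titled female edgeR called 0 genes. Yet Xist was 522 to 606 CPM in those titled C201R and at most 0.22 CPM in those titled WT. In a simulation of 43 lists by library name, the 1 list of 30 genes raised 1.3 times was called and 0 of the unchanged lists were. Genes were drawn independently there, so it does not measure false calls of lists whose members vary together. Over 100 splits of the real libraries, the title and library-name splits included, the median was 13 lists called with the preset correlation.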

Results

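Gene expression was measured in 12 libraries of polyadenylated RNA from whole spinal cord of mice aged 8 weeks. The titles describe 4 groups of 3 libraries each, set by genotype (wild type, WT, or heterozygous for the C201R change in Gars) and by sex. The genotype tag reads C201R+/+ for the libraries titled WT and C201R+/- for those titled C201R, and was read with the titles as wild type and heterozygous. Gars encodes glycyl-tRNA synthetase, the enzyme that attaches glycine to its tRNAs. The sum of estimated counts per library ran from 27175421 in WT_male 8 to 38271405 in WT_male 9, and 22057 to 22579 genes had a count above 0. In 4 of the 12 libraries the genotype in the title differed from the genotype written in the library name of the sample description. Libraries 4 and 9 were titled WT and named C201R, and libraries 11 and 12 were titled C201R and named WT. The title genotype was the main grouping, and the comparison was repeated with the library-name genotype and with the 8 undisputed libraries alone. Libraries are named by the group and number of their titles, and which genotype label is right is left open.

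Gars, the gene carrying the change (ENSMUSG00000029777, chromosome 6, 55038007 to 55079500 on the plus strand in GENCODE M21), was detected in every library. Its level was 150, 143, 146 and 152 CPM (counts scaled to a common library size) in the undisputed libraries labelled C201R, numbers 1, 2, 3 and 10. It was 130, 142, 135 and 135 CPM in the undisputed libraries labelled WT, numbers 5 to 8. Disputed libraries 4, 9, 11 and 12 had 155, 152, 139 and 137 CPM. A single-residue change need not alter the amount of mRNA, so this level does not check the genotype labels. By title the mean was 145 ± 5.97 CPM in C201R and 141 ± 9.99 CPM in WT (SD, n = 6 each), a log2 difference of 0.04 ± 0.05 (SE; edgeR adjusted p = 0.934). By library name it was 150 ± 4.2 CPM in C201R and 136 ± 4.25 CPM in WT, and Gars rose by 0.14 ± 0.03 on the log2 scale (edgeR adjusted p = 0.0343), a call that was lost under 14 of 24 other settings (edgeR, DESeq2 or limma adjusted p up to 0.444). In the 8 undisputed libraries the log2 difference was 0.14 ± 0.04 and did not pass (edgeR adjusted p = 0.208).

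Sex-linked transcripts disagreed with the titled sex in 6 of the 12 libraries. Xist, the noncoding RNA of the inactive X chromosome, was between 522 and 685 CPM in 6 libraries, in which the summed level of the 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty was at most 0.12 CPM. In the other 6 libraries Xist was at most 0.22 CPM and the Y-linked sum was between 126 and 164 CPM. The libraries with high Xist were numbers 1, 2, 3, 8, 11 and 12, of which 2, 3 and 8 were titled male. Libraries 4, 5 and 6 were titled female and carried the Y-linked transcripts. High Xist was seen in 5 of the 6 libraries titled C201R and in 1 of the 6 titled WT, so by title these transcripts were unevenly divided between the genotypes. By library name they were evenly divided, with 3 libraries of high Xist in each genotype. No library was regrouped on these values, and where sex entered a fit it was the sex of the titles.

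**Figure D1:**
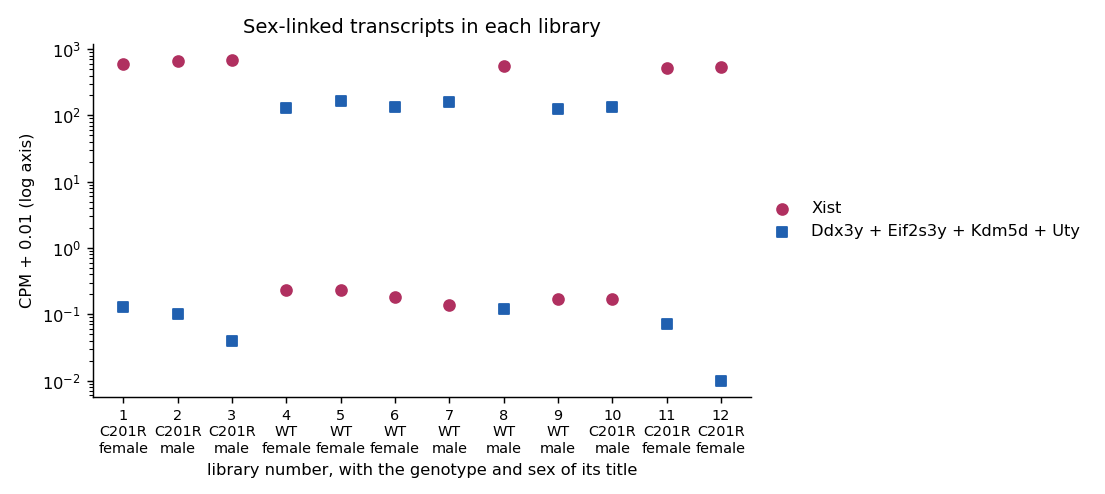
Levels of Xist (circles) and the summed Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty (squares) in each of the 12 libraries, in CPM plus 0.01 on a log axis, with the genotype and sex of each title under its number. Xist lies between 522 and 685 CPM in 6 libraries, 3 of them titled male, and the Y-linked sum lies between 126 and 164 CPM in the other 6, 3 of them titled female.

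The series asks which transcripts of the adult spinal cord change in mice carrying the Gars change. With the title genotype, no gene passed the threshold among the 17765 tested. The 10 genes of lowest p, none passing, included Fkbp5 and Zbtb16, both known glucocorticoid-responsive genes. Fkbp5 was 23.4 ± 2.05 CPM in C201R and 30.4 ± 1.86 CPM in WT (SD, n = 6 each; log2 difference -0.38 ± 0.06, edgeR adjusted p = 0.393). Zbtb16 was 19.8 ± 3.63 and 41.2 ± 15.4 CPM (log2 difference -1.03 ± 0.21, edgeR adjusted p = 0.542). The other 8 were Gareml, Herpud1, Ighg3, Whsc1l1, Clcn2, Mat2a, Swt1 and Tgfbr2, with edgeR adjusted p between 0.393 and 0.542. The edgeR quasi-likelihood test with titled sex as a term gave 1202 genes at an unadjusted p under 0.05, and DESeq2 called 18 genes (7 higher, 11 lower). That term does not adjust for the sex that Xist gives. Xist was high in 5 of the 6 libraries titled C201R and in 1 of the 6 titled WT. Differences by title, also those of the gene lists below, may therefore hold differences between the sexes, which was not tested. Title genotype also follows blocks of the library number, with 4 to 9 titled WT and 1 to 3 and 10 to 12 titled C201R. Effects of such blocks may enter these differences too, and were not tested.

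Of the 43 gene lists tested with the title genotype, 15 passed with a preset correlation between genes (8 higher, 7 lower). None passed with an estimated correlation, and none passed with fry. The lists of lowest p were glucocorticoid response and heat shock. In the first, 14 of 16 members were lower, with 7 past the threshold adjusted over the list alone and 0 over all genes (camera adjusted p = 2e-13, adjusted p = 0.0696 with an estimated correlation). In the second, all 14 members were lower (camera adjusted p = 2e-13, adjusted p = 0.357 with an estimated correlation). Of them 6 were past the threshold adjusted over the list alone and 0 over all genes. Hsph1, a member of the heat shock list, was 243 to 262 CPM in libraries 1 to 3. It was 302 to 372 CPM in all others, libraries 10 to 12 titled C201R among them. For this member the difference thus rests largely on libraries 1 to 3, which are C201R by both labels. All 15 members of the leukocyte list were higher (median log2 difference 0.51, camera adjusted p = 5.3e-09, adjusted p = 0.457 with an estimated correlation), and 5 of them passed when adjusted over the list alone. The integrated stress response list did not pass by title (median 0.07, camera adjusted p = 0.0635). The motor neuron list had a median of -0.08 (camera adjusted p = 7.98e-05, adjusted p = 0.563 with an estimated correlation).

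With the library-name genotype, 127 genes changed, 30 higher and 97 lower in C201R, with 2273 genes at an unadjusted p under 0.05. Of the 30 genes that rose, 11 belong to the list of the integrated stress response, the program that the transcription factor ATF4 drives when translation is impaired. Fgf21, a secreted metabolic hormone, had 733 counts over the 6 libraries named C201R and 2 counts over the 6 named WT, a ratio of 339 (95% counting interval 93.4 to 2800). Of the 23 motor neuron members 5 fell (camera adjusted p = 0.00166 with an estimated correlation), and of the 18 neurofilament and axonal cytoskeleton members 5 fell (camera adjusted p = 0.194 with an estimated correlation). Chodl, a marker of fast motor neurons, fell from 34.6 ± 6.52 CPM in WT to 13.1 ± 1.21 CPM in C201R (SD, n = 6 each), and Nefl, the light neurofilament subunit, from 2140 ± 105 to 1640 ± 39.8 CPM. None of the 127 genes was among the 18 that DESeq2 called by title.

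The integrated stress response list had 38 measured members, of which 32 were higher in C201R by library name. Of these, 11 passed over all genes, all higher, and 22 passed when adjusted over the list alone. The median log2 difference was 0.18, and it was 0.18 also with Fgf21 and Adm2 set to their bounds. The list passed with the preset correlation (camera adjusted p = 1.13e-45), with an estimated correlation (adjusted p = 3.42e-06) and with fry (adjusted p = 1.54e-07). Adm2, a secreted peptide, had 121 counts in C201R and 0 in WT, which is 37.3-fold higher against a floor of 3 counts over the group. The lower 95% counting limit of its ratio was 29.9. B4galnt2, a glycosyltransferase, was 0.953 ± 0.266 CPM in C201R and 0.178 ± 0.0277 CPM in WT (log2 difference 2.54 ± 0.20, edgeR adjusted p = 6.56e-05). Slc7a1, a cationic amino acid transporter, rose by 0.41 ± 0.03 (edgeR adjusted p = 6.56e-05) and Slc7a3, a related transporter, by 0.48 ± 0.08 (edgeR adjusted p = 0.0148). Sesn2, a stress-induced regulator of TORC1 signalling, rose by 0.38 ± 0.05, Chac1, which degrades glutathione, by 0.57 ± 0.07, and Gdf15, a secreted stress cytokine, by 3.26 ± 0.54, with edgeR adjusted p of 0.00133, 0.00268 and 0.0143. Gdf15 was low in both groups, at 0.445 ± 0.0917 and 0.0459 ± 0.0541 CPM.

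The cytosolic tRNA synthetase list had 18 of its 22 members higher by library name, with a median log2 difference of 0.06. Cars and Lars, the cysteinyl and leucyl enzymes, passed over all genes, rising by 0.18 ± 0.03 and 0.20 ± 0.04 (edgeR adjusted p = 0.0235 and 0.0408), calls that were lost under 8 and 16 of 24 other settings. When adjusted over the list alone 3 members passed. The list passed with the preset correlation (camera adjusted p = 0.000118) and with fry (adjusted p = 0.0451), and its call was lost with an estimated correlation (adjusted p = 0.353).

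The motor neuron list had 23 measured members, of which 18 were lower in C201R by library name. Over all genes 5 members passed, all lower, and 14 passed when adjusted over the list alone. The median log2 difference was -0.26 (camera adjusted p = 4.52e-27, adjusted p = 0.00166 with an estimated correlation). The called members were Ahnak2 (-0.75 ± 0.06, edgeR adjusted p = 6.56e-05), Chodl (-1.41 ± 0.12, edgeR adjusted p = 0.000112), Chat, the enzyme that makes acetylcholine (-0.45 ± 0.06, edgeR adjusted p = 0.00431), and the neuropeptide receptor Vipr2 (-0.91 ± 0.13, edgeR adjusted p = 0.00666). The fifth, Lhx4, was outside the naming rule and is named because it completes the count (-0.44 ± 0.07, edgeR adjusted p = 0.0131). Chat was 16.9 ± 1.31 CPM in C201R and 23.4 ± 1.67 CPM in WT. Among the members that did not pass, the log2 difference was -0.22 ± 0.07 for the choline transporter Slc5a7, 0.07 ± 0.16 for Mnx1, 0.00 ± 0.25 for Isl1 and -0.03 ± 0.09 for Mmp9, chosen after their values were seen.

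The neurofilament and axonal cytoskeleton list had 15 of 18 members lower by library name, and 5 passed over all genes. Nefl, Nefm and Nefh, the 3 neurofilament subunits, fell by 0.37 ± 0.03, 0.44 ± 0.05 and 0.37 ± 0.05 on the log2 scale (edgeR adjusted p = 0.000144, 0.000482 and 0.00406), and the microtubule-associated protein gene Map1b by 0.17 ± 0.03 (edgeR adjusted p = 0.0159; lost under 7 of 24 other settings). The fifth was Stmn2, a tubulin-binding protein gene of neurons (-0.19 ± 0.04, edgeR adjusted p = 0.0342; lost under 14 of 24). When adjusted over the list alone 7 members passed. The list passed with the preset correlation (camera adjusted p = 3.14e-11) and with fry (adjusted p = 0.0124), and not with an estimated correlation (adjusted p = 0.194). The pan-neuronal list had 11 of 12 members lower, by a median of only -0.04, with 1 member called, Stmn2 (camera adjusted p = 0.037, adjusted p = 0.516 with an estimated correlation). All 14 members of the heat shock list were lower, and Hspb1 and Bag3, a small heat shock protein and a co-chaperone, passed over all genes at -0.61 ± 0.11 and -0.38 ± 0.08 (edgeR adjusted p = 0.02 and 0.0467), calls lost under 7 and 15 of 24 other settings. When adjusted over the list alone 5 passed (camera adjusted p = 9.66e-11, adjusted p = 0.294 with an estimated correlation). Markers of other cell types were also higher in C201R by library name: all 15 leukocyte, 13 pericyte and smooth muscle, 9 blood and 9 fat members, with 0 called over all genes and 0 adjusted over the list alone. Their medians were 0.47, 0.21, 0.66 and 1.99, with adjusted p = 0.516, 0.294, 0.516 and 0.716 with an estimated correlation (camera). The fat list, whose median was the largest of all lists, did not pass with the preset correlation either (camera adjusted p = 0.0679). Its members Adipoq, Cfd and Plin1 were 32.2, 51.8 and 15.4 CPM in C201R_male 3. In any other library they were at most 1.24, 4.83 and 1.03 CPM, so their higher mean in C201R rests largely on C201R_male 3. The leukocyte list was higher by title as well, and the blood marker Slc4a1 did not follow the library name in each library. Slc4a1 was 17.3, 13.4 and 8.73 CPM in libraries 1 to 3. It was 6.24, 4.63 and 3.02 CPM in libraries 4, 9 and 10, and up to 7.89 CPM in those named WT.

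**Figure D2:**
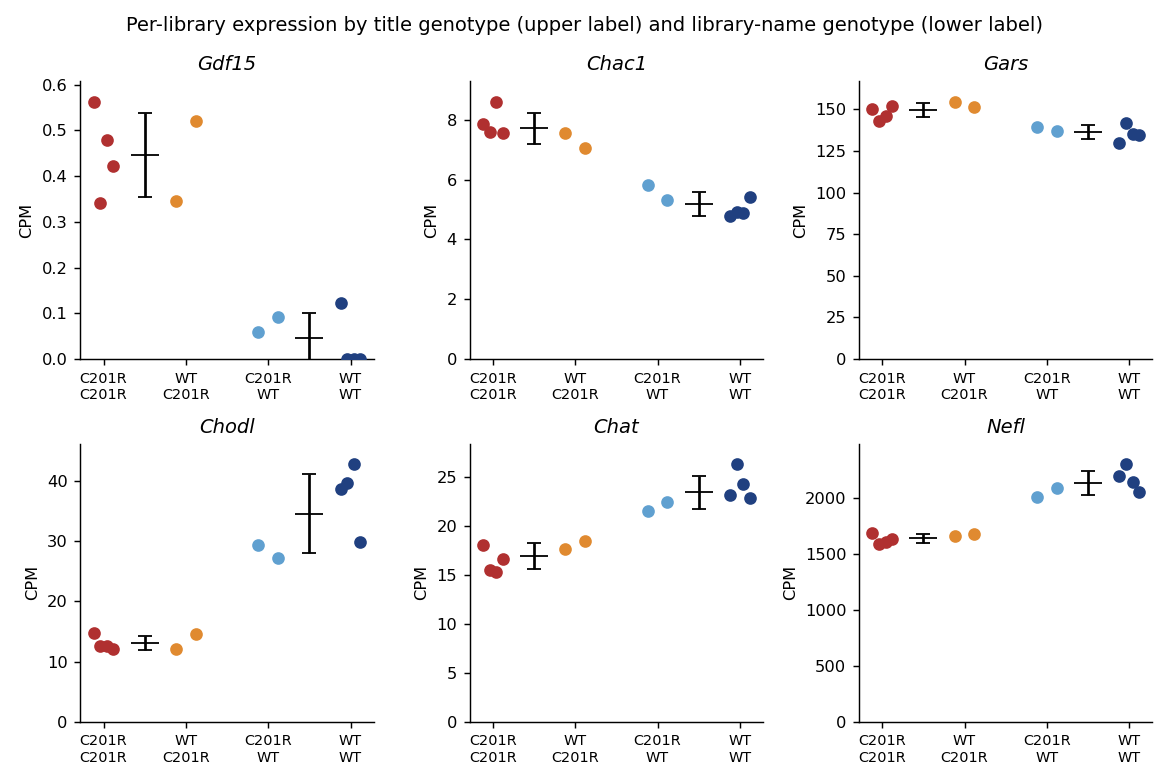
CPM of 6 genes in each of the 12 libraries (points), placed by the genotype of the title (upper label) and of the library name (lower label), with the mean and SD of the 6 libraries of each library-name genotype in black; each axis starts at 0. The disputed libraries lie with the undisputed libraries of their library-name genotype for Chodl, where those named C201R sit between 12 and 14.7 CPM and those named WT between 27.2 and 42.7 CPM.

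Outside these lists, the called genes with the largest changes included Cdsn (2.94 ± 0.32), Taf7l (1.89 ± 0.32) and Cass4 (1.47 ± 0.20) among those higher, with edgeR adjusted p of 0.000761, 0.0168 and 0.00351. Levels were low, at 0.391 ± 0.117 and 0.112 ± 0.0501 CPM for Taf7l and 1.23 ± 0.211 and 0.434 ± 0.1 CPM for Cass4 in C201R and WT. Among those lower were Cd7 (-1.73 ± 0.33), Aqp6 (-0.71 ± 0.11), the potassium channel gene Kcnj14 (-0.70 ± 0.04), Cd24a (-0.68 ± 0.14), Palm3 (-0.67 ± 0.09), Slc10a4 (-0.66 ± 0.08) and Mrvi1 (-0.66 ± 0.10), with edgeR adjusted p from 9.01e-06 for Kcnj14 to 0.0402 for Cd24a. Dffa, which encodes an inhibitor of a DNA fragmentation factor, fell by 0.44 ± 0.04 (edgeR adjusted p = 0.000112). The count moved with the libraries included: it was 57, 84, 58, 83, 54, 67, 221 and 81 without libraries 1, 3, 4, 5, 7, 8, 9 and 12 in turn, and 12 without the 4 libraries that held the most skeletal muscle transcripts, a setting chosen after seeing the data. Of the 38 called genes named by the rule, 8 passed under every other setting run: Fgf21, Kcnj14, Slc7a1, Ahnak2, Chodl, Dffa, Nefl and Nefm. The calls of Cd7 and Taf7l were lost under 16 and 8 of 23 settings, of Gdf15 under 5 of 23, of Cd24a under 12 of 24 and of Slc7a3 under 7 of 24.

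The library number, from 1 to 12, was also fitted as a linear term, a setting chosen after seeing the data. Beside the library-name genotype 1134 genes followed the number (edgeR), against at most 9 in any other of 50 orders of the numbers, and without a genotype term 299 did. A large structure along the number is therefore present, and its cause was not tested. With the number in the fit 235 genes passed for the library-name genotype, 56 higher and 179 lower, of which 93 were among the 127. All 127 kept their sign, and their median absolute log2 difference was 0.28 in place of 0.29. The integrated stress response and motor neuron lists passed with an estimated correlation (camera adjusted p = 0.000405 and 0.00307). The medians of the leukocyte, blood and fat lists became 0.06, 0.01 and 0.02. With the title genotype and the number in the fit 8 genes passed, including Fkbp5 and Gareml and 0 of the 127.

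The 8 undisputed libraries, 4 of each genotype, gave 29 genes, 6 higher and 23 lower, with 2304 at an unadjusted p under 0.05. Xist was high in libraries 1, 2 and 3 of those labelled C201R and in library 8 of those labelled WT. Sex-linked transcripts were thus unevenly divided here, and the term for titled sex did not adjust for it. Because these libraries are part of the 12, the 23 genes shared with the 127 are not independent of them. All 127 genes had the same sign of difference in the 8 libraries. The 6 genes that rose were Fgf21, Cdsn, Slc7a1, B4galnt2, Chac1 and Zc3h6, a zinc finger gene (0.68 ± 0.09, edgeR adjusted p = 0.0395). Those that fell included Chodl (-1.50 ± 0.10), Chat (-0.53 ± 0.06), Nefl (-0.39 ± 0.03), Kcnj14 (-0.75 ± 0.05), and Dio2, the enzyme that activates thyroid hormone (-0.73 ± 0.06), with edgeR adjusted p of 0.00162, 0.0168, 0.00162, 0.00118 and 0.00394. The integrated stress response list passed with an estimated correlation (adjusted p = 0.00515), and the motor neuron list did not (adjusted p = 0.0527).

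**Figure D3:**
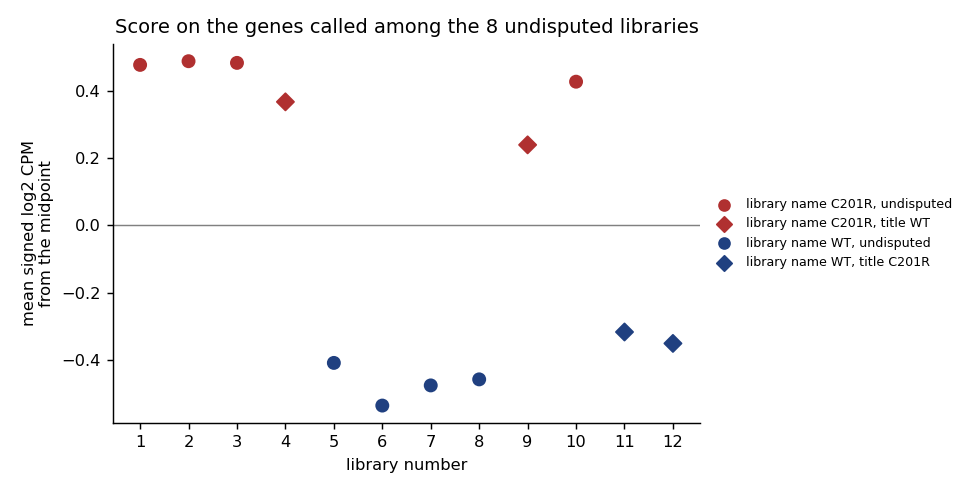
Score of each library on the 29 genes called among the 8 undisputed libraries, as the mean log2 CPM from the midpoint of the 2 genotypes, signed so that C201R is positive, against the library number. Circles are undisputed libraries and diamonds disputed ones, red where the library name is C201R and blue where it is WT; the disputed libraries score 0.368, 0.24, -0.317 and -0.351.

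The titles also allow the genotype to be compared within each titled sex, which the sex-linked transcripts contradict in 6 of the 12 libraries. Among the libraries titled female, the C201R ones (1, 11 and 12) had high Xist and the WT ones (4, 5 and 6) did not. Genotype cannot be told apart from sex there, and the libraries titled male mixed both kinds. The counts below therefore do not describe genotype within 1 sex. Among the libraries titled female, 3 against 3, no gene passed edgeR, with 695 genes at an unadjusted p under 0.05. The genes of lowest p, none passing, were Frmd5 (0.17 ± 0.04), Pde7b (0.22 ± 0.05) and the relaxin receptor gene Rxfp1 (0.64 ± 0.15), each with an edgeR adjusted p of 1. DESeq2 called 2 genes, the Y-linked Ddx3y and Eif2s3y, both lower in C201R. Those are the transcripts that were present in libraries 4, 5 and 6, titled WT and female. Among the libraries titled male, 3 against 3, no gene passed edgeR, with 1309 at an unadjusted p under 0.05, and DESeq2 called 29. The genes of lowest p were Mark3 (-0.22 ± 0.04), Zbtb16 (-1.45 ± 0.25) and Fkbp5 (-0.46 ± 0.08), each with an edgeR adjusted p of 0.541. With the library-name genotype edgeR called 20 genes among the libraries titled female, where 2 libraries named C201R stood against 4 named WT, and 14 among those titled male, where it was 4 against 2.

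The difference between the genotype effects of the titled sexes was tested as an interaction. It rests on the same titled sexes, so it does not test a difference between females and males. No gene passed edgeR, with 758 at an unadjusted p under 0.05, and DESeq2 called 2, again Ddx3y and Eif2s3y. The genes of lowest p included Jun, an immediate early transcription factor gene (-0.29 ± 0.06, edgeR adjusted p = 0.966), and Mark3 (0.20 ± 0.05, edgeR adjusted p = 0.966). With the library-name genotype no gene passed, with 612 at an unadjusted p under 0.05.

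Between the titled sexes no gene passed edgeR, with 981 at an unadjusted p under 0.05, and DESeq2 called 7. Xist was high in libraries 1, 11 and 12 of those titled female and in 2, 3 and 8 of those titled male. The comparison therefore does not set females against males. With title genotype as a term, the difference in Xist, female minus male, was -2.83 ± 2.41 on the log2 scale (edgeR adjusted p = 0.903), and in Ddx3y -1.49 ± 1.54 (edgeR adjusted p = 0.91). These fitted values depend on that term, since both titled sexes held libraries with and without each transcript. Kdm5d, Uty, Kdm6a and Tsix did not pass either, with edgeR adjusted p between 0.903 and 0.92. The autosomal genes of lowest p were Ddn (0.77 ± 0.15), Sptbn5 (0.73 ± 0.15), Spon2 (0.82 ± 0.17), Spint1 (0.62 ± 0.13) and Ccdc37 (0.51 ± 0.11) among those higher in libraries titled female. Those lower were Ccdc3 (-0.30 ± 0.06), Nnat (-0.23 ± 0.05), Lrrc55 (-0.20 ± 0.05), Nol4 (-0.20 ± 0.05) and Dner (-0.12 ± 0.03). All 10 had an edgeR adjusted p of 0.79.

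Genes near Gars were compared with all others, because sequence linked to an introgressed allele can differ between genotypes. By library name, 1 of 223 tested genes within 20 Mb of Gars was called, against 124 of 17262 elsewhere, with Gars itself left out (Fisher's exact test, two-sided, odds ratio 0.623, 95% interval 0.0156 to 3.57, p = 1). The gene was Chrm2, a muscarinic acetylcholine receptor gene (36388084 to 36528414 on chromosome 6; -0.19 ± 0.03, edgeR adjusted p = 0.0108, a call lost under 7 of 24 other settings). At an unadjusted p under 0.001 the numbers were 3 of 223 and 202 of 17262 (Fisher's exact test, odds ratio 1.15, p = 0.748). By title no gene was called, and at an unadjusted p under 0.001 there were 1 of 223 and 25 of 17262 (Fisher's exact test, odds ratio 3.11, p = 0.284). Without C201R_female 12 the odds ratio by title was 6.83 (Fisher's exact test, p = 0.00375), from 4 of 223 against 46 of 17262.

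Transcripts of neighbouring tissues and of blood varied between libraries. Skeletal muscle markers took 0.118 ± 0.141% of the counts in C201R and 0.117 ± 0.109% in WT by title (SD, n = 6 each; exact permutation test, two-sided, adjusted p = 0.975). By library name they took 0.131 ± 0.132% and 0.104 ± 0.118% (exact permutation test, adjusted p = 0.818). Peripheral myelin markers took 0.199 ± 0.0344% and 0.24 ± 0.0658% by library name (exact permutation test, adjusted p = 0.367), and globin transcripts 0.133 ± 0.0855% and 0.0863 ± 0.0349% (exact permutation test, adjusted p = 0.367). None of the 7 composition measures passed by title or by library name. The smallest p that the splits allow was 0.005 by title and 0.00216 by library name.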

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

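The outlier check compared the gap between the most extreme library of a group of 6 and its nearest neighbour with the range of the group. Over 126 groups it marked 3 values, and chance marks about 1 in 20 groups, or 6.3 here. The groups by library name were added after seeing the data.

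Zbtb16 in the libraries titled C201R was 27.1 CPM in C201R_female 12 and between 17.3 and 19.2 CPM in the other 5, a gap of 0.798 of the range. Lars in the libraries named C201R was 45.4 CPM in WT_male 9 and between 49.6 and 51.7 CPM in the other 5, a gap of 0.678 of the range. Nefh in the libraries named WT was 1480 CPM in WT_female 6 and between 1229 and 1312 CPM in the other 5, a gap of 0.671 of the range.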

How the results depend on the processing

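The settings for the library name were chosen after seeing the data, except the 8 undisputed libraries. By title, the count of 0 called genes over both sexes stayed at 0 under the other scalings, filters, TPM units, weights, the surrogate variable, no sex term and each left-out library (0 to 0). The library number as a term, chosen after seeing the data, gave 8, DESeq2 called 18, the library-name genotype 127 and the 8 undisputed libraries 29. Among the libraries titled female these 3 settings gave 2, 20 and 1 (Fgf21), and 0 to 2 with a library left out. The call of Fgf21 compares 1 C201R library with 2 WT libraries and assumes that the lone library varies like the other groups. Among those titled male they gave 29, 14 and 5 (Fgf21, Dio2, Kcnj14, Chodl and Nefl), and 0 to 3. DESeq2 called 2 genes for the difference between the sexes, with 0 to 2 by left-out library, and 7 between the titled sexes, with 0 to 1. Without WT_male 7 the calls were Apold1 and Egr1 among females, Zbtb16, Apold1 and Tob2 among males, and Apold1 and Tob2 for the difference. Single calls for the difference came without C201R_female 1 (Gm24012) and C201R_female 12 (Tmem45b), and between the sexes without WT_female 4 (Smtn).

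By library name, the 127 genes became 335 with DESeq2 (120 shared), 235 with the library number as a term (93 shared), 41 with TPM + 1, 42 with TPM + 0.1, 29 in the 8 undisputed libraries and 12 without the 4 libraries with the most muscle transcripts, all 12 shared. The last 2 settings have fewer libraries. For the others the cause was not tested. Leaving out 1 library gave 54 to 221: 57 without C201R_female 1, 84 without C201R_male 3, 58 without WT_female 4, 83 without WT_female 5, 54 without WT_male 7, 67 without WT_male 8, 221 without WT_male 9 and 81 without C201R_female 12. Of its 38 named called genes, 8 kept the call under every alternative run (Fgf21, Kcnj14, Slc7a1, Ahnak2, Chodl, Dffa, Nefl and Nefm), and 0 changed direction. Gars lost its call in 14 of 24 alternatives.

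The 15 lists called by title became 0 with an estimated correlation and 0 with fry, and 11 to 19 with a library left out. The 16 called by library name became 2 and 4, and 14 to 18. At an unadjusted p under 0.001, the odds ratio near Gars by title ran from 0 to 7.77 with a library left out, and passed without C201R_female 12 (6.83). By library name it ran from 0.467 to 1.32. No paired analysis was possible because the library numbers run from 1 to 12 and no number is shared between groups.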

Other observations

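The tests on the disputed labels (of which the test of drift took the place of 3 earlier ones on scores that left it open or rested on genes the same libraries chose), the test of unequal motor neuron changes (which took the place of tests on Chat, Chodl and Slc5a7 alone, a choice of genes made from the pattern), and the splits for both sexes, the library name, the 8 libraries and the titled sexes were chosen after the result was seen, and the gene lists by library name were added after seeing the data. The other tests were written before their results were seen. Of the lists not yet described, cholesterol synthesis had 23 of 25 members lower by library name, 0 called over all genes and 12 adjusted over the list alone (median -0.13, camera adjusted p = 9.3e-10, adjusted p = 0.353 with an estimated correlation). The members of lowest p were Sc5d and Sqle, both enzymes of sterol synthesis, at -0.17 and -0.14 (edgeR adjusted p = 0.0591 and 0.0649). The interferon response list had 26 of 30 members higher (median 0.18, adjusted p = 0.516 with an estimated correlation), and the oligodendrocyte myelin list 18 of 20 lower (median -0.07, adjusted p = 0.674 with an estimated correlation). Adipoq, an adipocyte hormone, was 32.2 CPM in C201R_male 3 and at most 1.24 CPM in the other 11 libraries.

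The genotype labels of libraries 4, 9, 11 and 12 conflict, and each library was scored on the 29 genes called among the 8 undisputed libraries, which do not include these 4. All 4 lay on the side of their library name and 0 on the side of their title, with scores of 0.368 and 0.24 for libraries 4 and 9 and -0.317 and -0.351 for 11 and 12. A linear drift along the library number as the whole cause of the library-name difference is argued against by the 93 of 127 genes that stayed called with the number in the fit, but not as a part of it, since 1134 genes followed the number. On 100 genes chosen with 2 of libraries 5 to 8 left out, libraries 9 and 10 both scored above those 2 in 3 of 6 choices. The other 3 were those leaving out library 8, which scored 0.099, 0.044 and 0.149 there. In those 3 the disputed libraries lay on the side of their titles. Libraries 4 and 9 scored -0.196 to -0.097, and 11 and 12 scored 0.065 to 0.221. Undisputed library 10 scored -0.15 to -0.093, away from its C201R label. Libraries 1 to 3 had high Xist and 5 to 7 did not, so these 3 choices cannot separate genotype from sex. Where library 8 helped to choose, library 4 scored 0.108 to 0.148, 12 scored -0.417 to -0.181, and 9 and 11 lay on both sides of 0. A candidate explanation, as a hypothesis, is that the titles of these 4 libraries carry the wrong genotype. High Xist was seen in 3 libraries of each library-name genotype, which is the balance of sexes that the titles describe. By title it was seen in 5 libraries of C201R and 1 of WT. That balance goes with the library names but does not test genotype, since other divisions of the libraries can be balanced too. Processing in blocks of the library number (1 to 4 and 9 to 10 against 5 to 8 and 11 to 12) would split expression in the same way, and the labels used here give no batch.

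Motor neuron genes were lower by library name. Loss of motor neurons cannot be told apart: the 23 members changed unequally (exact permutation test, p = 0.00216, the smallest the 924 splits can give), but other cells of the cord also express some members, so unequal changes do not exclude it. A lower share of neuronal RNA is argued against by the pan-neuronal median of -0.035 (bootstrap 95% interval over its genes -0.068 to -0.021), above the bound set beforehand. That interval leaves out the spread between libraries, so the argument is a weak one. A different level of the cord cannot be told apart: Hox genes of groups 9 to 13 differed from groups 4 to 6 by 0.164 in median (interval 0.059 to 0.53), between the bounds set beforehand. Altered transcription in motor neurons may also contribute and was not tested.

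Integrated stress response genes were higher by library name. Activity or dissection stress at death would raise the immediate early list, which had a median of -0.133 (bootstrap 95% interval over its genes -0.263 to -0.002). The median shows no such rise, but the interval leaves out the spread between libraries. Fos, a list member, was 21.6 to 26.1 CPM in libraries 4 to 7 and 11.8 to 16.5 CPM in the others. The test therefore cannot decide. A trend on GC content and length is argued against, since the 11 called members kept 94.7% of their median log2 difference after such a trend was removed. A different share of leukocytes or blood is argued against as the whole cause. With the library number in the fit, a setting chosen after seeing the data, the medians of both lists nearly vanished. The integrated stress response list still passed there with an estimated correlation. A different makeup of other cells, with pericyte markers higher, and processing in blocks of the library number stay open. A response to the mutant synthetase may also contribute, as a hypothesis that was not tested and that holds only if the library names are right.

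Other splits of the same libraries bear on chance. By library name, 1 of 100 splits, the real one, gave 127 genes, and the highest other gave 13, which argues against chance. In the 8 undisputed libraries 1 of 35 splits gave 29 genes, the real one, against 20 in the highest other. That also argues against chance but cannot exclude it, since 1 of 35 is the smallest share those splits allow. Both tests were chosen after the result was seen. Where 0 genes were found every split gives at least as many, so the counts of 100 of 100 by title, 50 of 50 for the titled sexes and 50 of 50 for the difference between the sexes say nothing about chance. Their highest other splits gave 127, 5 and 0 genes. The 127 came from the library-name split, included by design beside drawn ones, and point to a structure of the samples that the titles do not follow. Among females and among males the 10 splits are too few for a share under 0.05, with 0 genes and a highest other of 0 and 10. For gene lists with the preset correlation, 41 of 100 splits gave at least the 15 found by title and 27 of 100 at least the 16 found by library name, with a highest other of 21, so chance cannot be excluded for either count. With an estimated correlation 2 of 100 splits gave 2 or more lists, the library-name split included.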
